A study of Caenorhabditis elegans with 6 samples.

How the data were processed

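The values were log2 CPM, deposited by the authors as 1 table of 6 libraries; limma and the WBcel235 genome build are named in the submitters' processing notes, and the column names per the file headers point to a subread aligner, whose version is not given in the sources used here. The labels' protocols state extraction of total RNA from whole animals and paired-end sequencing; the counter, the strand setting and the filter on low genes are not given in the sources used here. In the deposited log2 values, 2 to the power of each value times a constant per library, minus 0.5, was a whole number within 0.01 for 100% of genes in each library, the form that limma's voom writes, so reads per gene could be recovered. The constants differed from the library totals by factors of 0.914 to 1.093, so a scaling between libraries had been applied before deposit. The 10 most abundant genes took 5.92% to 9.9% of reads.

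The table held 12799 rows, of which 15 name no gene and took at most 0.0079% of a library; they were left out. All 12784 gene identifiers matched the WBcel235 annotation. No gene had 0 reads in any library, and the lowest third-highest value of a gene was 0.938 CPM, so genes of low expression had been removed before deposit. Within groups, pairs of libraries differed by a chi-square of 35.7 to 183 per degree of freedom, above sampling noise, so no pair looked like 1 library entered again and each was counted once; this does not show that the libraries are independent.

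Genes with a log2 value above 0 in at least 3 of the 6 libraries were tested, 12739 genes with 45 left out. The test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend) on the deposited log2 values, JUb19 minus OP50, 3 libraries against 3, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on this log2 scale, with the offset of 0.5 reads. SE is that of limma's moderated test. Gene lists, 38 in all, were fixed from textbook knowledge before the data were examined and tested with limma's camera (preset correlation 0.01, lists of at least 3 tested genes), with an estimated correlation and fry beside it. Lists are compared with the other genes by camera, not by fry. Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 read the table, and matplotlib 3.10.9 drew the plots.

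Named genes followed a rule fixed before the data were examined: the 8 highest and 8 lowest log2 fold changes among called genes without overlap between groups and above the median expression; up to 3 called members with the largest change in each list described, or the member with the smallest p where none passed; and a fixed set of defence, diet, stress and stage genes. Alternatives were other filters, scalings and variance models, the replicate number as a block, leaving out each library, an effect size limit, and list tests; voom weights on the recovered reads, log2(CPM + 1) and a vitellogenin covariate were chosen after seeing the data. The functions were tested on simulated data with 12560 genes that passed the filter. In them 99 genes changed by a log2 fold of 1 and 100 by 2. Of these 47.5% and 89% were recovered, with 6 false calls, and 0 calls were made where nothing changed. The simulated noise was independent between genes, with 1 SD per gene for both groups. In the real libraries the median SD over genes was 0.238 on JUb19 and 0.152 on OP50. The first principal component of the real libraries held 60.2% of the variance. These rates therefore need not hold for the real data. At the shallowest library, 3 reads correspond to 0.082 CPM; this floor covers counting error only.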

Results

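Transcripts of whole wild-type Caenorhabditis elegans were measured by RNA sequencing after growth on 1 of 2 bacterial foods. JUb19 is a Stenotrophomonas strain of the worm's natural gut flora, and OP50 is the Escherichia coli strain used as standard laboratory food. There were 3 libraries of animals fed JUb19, collected at 50 h, and 3 libraries of animals fed OP50, collected at 48 h. The submitters chose the later collection on JUb19 to bring the animals closer in development, so food and collection time form a single contrast. Reads assigned to genes came to 39530857, 34746263 and 43423333 in JUb19 replicates 1, 2 and 3, and to 43259150, 40604519 and 37545423 in OP50 replicates 1, 2 and 3. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

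The genes that changed between animals on JUb19 and on OP50 included lysozymes, detoxification enzymes, and genes of propionate metabolism, the germline and the cuticle. Of 12739 genes tested with limma, 698 changed at a Benjamini-Hochberg adjusted p under 0.05, 235 higher and 463 lower on JUb19. Among the more abundant genes, Y41C4A.32, the aspartyl protease gene asp-12 and the stearoyl-CoA desaturase gene fat-7 rose the most, with log2 fold changes of 4.39 (SE 0.37), 2.35 (SE 0.25) and 2.04 (SE 0.27). The P-glycoprotein transporter genes pgp-6 and pgp-5 fell by 3.80 and 3.42 on the log2 scale (SE 0.37 and 0.36), and the C-type lectin gene clec-47 fell by 3.19 (SE 0.18). Log2 fold changes were -2.89 for the myo-inositol transporter gene hmit-1.1 and -2.47 for both E03H4.8 and dod-17. The gap junction gene inx-3, chtl-1 and meg-2, a gene of germline granules, rose by 1.32, 1.20 and 1.18. Of the genes in this paragraph, hmit-1.1, chtl-1 and meg-2 lost the call without OP50 replicate 1, 2 or 3 (adjusted p = 0.0517 to 0.148), inx-3 without OP50 replicate 2 or 3 (adjusted p = 0.0733 and 0.0561) and E03H4.8 without OP50 replicate 2 (adjusted p = 0.064).

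All 698 called genes had groups that did not overlap, as did 5368 of all tested genes, or 42.1%. Without any group difference this share averages 10% over all splits. Genes move together, so it can lie far from 10% in a single split, and it was not computed for the other splits. The number of called genes depended on single libraries. It was 1713 without JUb19 replicate 1, and 199, 103 and 160 without OP50 replicate 1, 2 or 3. Quantile normalization gave 1436 genes, of which 51.8% were higher, against 33.7% in the deposited scaling. JUb19 replicate 3 lay apart on the first principal component, at -66.1 against -7.2 and -22 for the other JUb19 libraries and 31 to 32.3 for OP50. Without it, 672 genes passed, 535 of them among the 698.

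The lysozyme genes lys-10, ilys-3 and ilys-2 rose on JUb19. The transcript of lys-10 (WBGene00003099, chromosome IV, 8332826 to 8333518, WBcel235) had 3510, 1022 and 1888 reads in the JUb19 libraries and 6, 4 and 14 in the OP50 libraries, a log2 fold change of 7.95 (SE 0.49, adjusted p = 0.000136). The invertebrate-type lysozyme genes ilys-3 and ilys-2, which lie close together on chromosome IV, rose by 6.00 (SE 0.68) and 3.40 (SE 0.42), with adjusted p = 0.00287 and 0.00447. In ilys-3 the OP50 libraries held 8, 2 and 1 reads, so the size of that fold is loosely set. Of 50 tested lysozymes and antimicrobial peptides 3 rose and 8 fell, 3 and 9 adjusted over the list alone; the median log2 fold change was -0.38 and the mean -0.04. Medians on JUb19 were -0.04, -0.23 and -0.74 in replicates 1, 2 and 3. Camera put this list past the threshold in the lower direction (adjusted p = 0.0176) but not with an estimated correlation (adjusted p = 0.718). The call also ended without JUb19 replicate 3 (adjusted p = 0.0756), OP50 replicate 1 (adjusted p = 0.115) or OP50 replicate 3 (adjusted p = 0.0518), the median was -0.13 without JUb19 replicate 3, and 5 members were lower without JUb19 replicate 2 and 1, 1 and 2 without OP50 replicate 1, 2 or 3.

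C-type lectins, sugar-binding proteins that are often regulated by bacteria, moved both ways. Of 84 tested members 12 fell and 6 rose, or 28 and 7 adjusted over the list alone, with a median of -0.58. Besides clec-47, clec-169 fell by 3.48 (SE 0.39), while clec-70 rose by 2.96 (SE 0.44). The list passed by camera (adjusted p = 0.000283) and not with an estimated correlation (adjusted p = 0.667). Leaving out OP50 replicate 1, 2 or 3 left 6, 4 and 6 members lower and 2, 0 and 1 higher, while 21 were lower without JUb19 replicate 1, the median was -0.36 without JUb19 replicate 3 and no mean-variance trend left 2 higher. The gene clec-70 lost its call without OP50 replicate 2 (adjusted p = 0.0558). A further list of pathogen response genes was named for the p38 PMK-1 pathway, a conserved branch of intestinal immunity. In it 6 of 14 members fell and 0 rose, or 8 and 1 adjusted over the list alone. Whether each member depends on PMK-1 was not tested, so the list does not measure the output of that pathway. Among its members irg-1 fell by 3.03 (SE 0.53), cyp-35C1 fell by 2.94 (SE 0.49), and dod-24 fell from 63.4 CPM on OP50 to 13.3 CPM on JUb19. The list median was -0.90, with adjusted p = 0.000289 by camera and adjusted p = 0.697 with an estimated correlation. Its medians in JUb19 replicates 1, 2 and 3 were -0.73, -0.87 and -1.56, beside -0.33, -0.49 and -0.68 for intestinal markers. Without OP50 replicate 1, 2 or 3, 4, 1 and 4 members of this list were lower, and without JUb19 replicate 3 or with quantile normalization 1 was higher. The call of irg-1 ended without each of these (adjusted p = 0.0547, 0.0768 and 0.0705), and that of cyp-35C1 without OP50 replicate 2 or 3 (adjusted p = 0.0601 and 0.0672). The PMK-1 reporter gene T24B8.5, also called sysm-1, stood at 5.52 CPM on JUb19 and 1.36 CPM on OP50 (log2 fold change 1.62, SE 0.61, adjusted p = 0.116). It was called without JUb19 replicate 3 (adjusted p = 0.0098) and with quantile normalization (adjusted p = 0.0495). The gene irg-4 stood at 11.6 and 15.6 CPM (adjusted p = 0.368).

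In the propionate shunt, which breaks down propionate where vitamin B12 is scarce, 5 of 8 tested genes fell on JUb19 and 0 rose, 7 and 0 adjusted over the list alone. The dehydrogenase gene acdh-2 fell by 4.44 (SE 0.55), hach-1 by 1.35 (SE 0.16) and hphd-1 by 1.29 (SE 0.13), and acdh-1, the first step of the shunt and a common reporter of dietary B12, fell by 0.65 (SE 0.12, adjusted p = 0.0245). The median was -0.96 and lay between -1.09 and -0.90 in each JUb19 library, including replicate 3. Intestinal markers had medians of -0.33, -0.49 and -0.68 in JUb19 replicates 1, 2 and 3. The propionate shunt list passed by camera (adjusted p = 2.8e-06) and not with an estimated correlation (adjusted p = 0.535). The call of acdh-1 ended without OP50 replicate 1, 2 or 3 (adjusted p = 0.0966, 0.0687 and 0.0772), and the other named members kept theirs with each library left out. In the B12-dependent route that the shunt bypasses, 0 of 6 genes passed by limma, 0 adjusted over the list alone and 1 at an unadjusted p under 0.05, with a median of 0.02 that ran from -0.10 to 0.10 when each library was left out; mce-1 had the smallest p, at a log2 fold change of -0.39 (adjusted p = 0.116).

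In the methionine and S-adenosylmethionine cycle 3 of 17 genes fell, 6 adjusted over the list alone. The cystathionine lyase gene cth-1 fell by 2.41 (SE 0.18), the nuclear receptor gene nhr-114 fell by 1.16 (SE 0.19) and the adenosylhomocysteinase gene ahcy-1 by 0.90 (SE 0.20). The methionine synthase gene metr-1, which needs B12, stood at 645 CPM on JUb19 and 615 CPM on OP50 (adjusted p = 0.71). Medians were -0.48, -0.23 and -0.20 in JUb19 replicates 1, 2 and 3, beside the intestinal markers at -0.33, -0.49 and -0.68. The list passed by camera (adjusted p = 0.000513) and not with an estimated correlation (adjusted p = 0.667). With OP50 replicate 1, 2 or 3 left out, 1 member of the list passed, against 5 lower with quantile normalization, and nhr-114 had adjusted p = 0.0549, 0.0748 and 0.0601, and ahcy-1 adjusted p = 0.107, 0.134 and 0.0672. Without JUb19 replicate 1 or 2, ahcy-1 also lost its call (adjusted p = 0.0595 and 0.0773).

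Fat metabolism genes went both ways. In fatty acid breakdown 5 of 40 genes rose and 7 fell, 9 and 9 adjusted over the list alone, with ech-9 higher by 2.80 (SE 0.34) and the acyl-CoA synthetase gene acs-2 lower by 1.94 (SE 0.24). Without OP50 replicate 1, 2 or 3 there were 3, 1 and 2 higher and 3, 3 and 3 lower members, without JUb19 replicate 2 there were 3 higher, and no mean-variance trend gave 2 higher and 4 lower. In synthesis and desaturation 1 of 22 rose, fat-7, and 1 fell, acs-1, by 2.00 (SE 0.21), and 2, 2 and 3 members were lower without JUb19 replicate 1, 2 or 3, 2 higher without JUb19 replicate 2 and 4 lower with quantile normalization. Camera, which tests for a shift in one direction, placed neither list past the threshold (adjusted p = 0.941 and 0.357). Fry for mixed directions passed both (adjusted p = 0.000119 and 0.00136), but it does not compare a list with other genes.

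Of 48 UDP-glucuronosyltransferases, enzymes that couple sugars to foreign compounds, 21 fell and 0 rose, 27 and 1 adjusted over the list alone, with a median of -0.83. The transcript of ugt-53 fell by 3.67 (SE 0.25), ugt-26 fell by 3.02 (SE 0.18) and ugt-31 fell by 2.97 (SE 0.30). The list passed by camera (adjusted p = 3.21e-11), not with an estimated correlation (adjusted p = 0.535), and held 9, 8 and 9 lower members without OP50 replicate 1, 2 or 3 and 13 with no mean-variance trend. Without JUb19 replicate 3, 2 members were higher. Intestinal markers were lower in the same libraries: their medians in JUb19 replicates 1, 2 and 3 were -0.33, -0.49 and -0.68, beside -0.64, -0.74 and -1.09 for the UDP-glucuronosyltransferases and -0.34, -0.25 and -0.53 for glutathione S-transferases. Among 22 glutathione S-transferases 4 fell and 18 did not pass, with 9 lower and 1 higher adjusted over the list alone, among them gst-10 by 2.36 (SE 0.22), gst-9 by 1.61 (SE 0.33) and gst-4, a reporter of oxidative stress, by 1.29 (SE 0.18). That list had adjusted p = 0.0242 by camera and adjusted p = 0.697 with an estimated correlation, and its call ended without JUb19 replicate 3 (adjusted p = 0.0566) or OP50 replicate 2 (adjusted p = 0.0746). The calls of gst-9 and gst-4 ended too, gst-9 at adjusted p = 0.0573 to 0.138 without JUb19 replicate 2 or any OP50 library, and gst-4 at adjusted p = 0.053 without OP50 replicate 3. The lower glutathione S-transferases numbered 2 without JUb19 replicate 2 or OP50 replicate 1 or 2 and 1 without OP50 replicate 3. Among 42 cytochrome P450 genes 4 fell, 1 rose and 37 did not pass, 4 and 3 adjusted over the list alone. The median was 0 and the mean -0.15, with adjusted p = 0.946 by camera. Fry for mixed directions, which does not compare the list with other genes, gave adjusted p = 8.29e-05. The lower P450 members numbered 2, 1 and 1 and the higher 0 without OP50 replicate 1, 2 or 3, while 7 were lower and 3 higher without JUb19 replicate 1, 2 were higher without JUb19 replicate 3, no mean-variance trend left 2 lower, and quantile normalization put the median at 0.25 with 4 higher. In this family cyp-35A5 fell by 3.13 (SE 0.38) and cyp-35A3 by 3.05 (SE 0.63), the latter without a call when any OP50 library was left out (adjusted p = 0.0897 to 0.116). The metallothionein gene mtl-2 fell by 3.95 (SE 0.42).

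Of 31 oocyte and eggshell genes 13 rose and 0 fell, 30 and 0 adjusted over the list alone, with a median log2 fold change of 0.69. The germline determinant nos-2 rose by 0.97 (SE 0.20), the eggshell proteoglycan gene cpg-1 by 0.93 (SE 0.19) and oma-2, a gene of oocyte maturation, by 0.90 (SE 0.19). Medians in JUb19 replicates 1, 2 and 3 were 0.50, 0.50 and 1.06 above the OP50 mean, so replicate 3 lay apart. In the same animals the medians of intestinal and body wall muscle markers were -0.48 and -0.38. Both lists were lower by camera (adjusted p = 3.75e-05 and 0.0324) but not with an estimated correlation (adjusted p = 0.673 and 0.718). The muscle call by camera also ended without JUb19 replicate 1 or 2 or OP50 replicate 3 (adjusted p = 0.0742, 0.126 and 0.059). The oocyte list passed by camera (adjusted p = 7.55e-15) and not with an estimated correlation (adjusted p = 0.697). Member calls, though not the size of the change, rested on all OP50 libraries and on the variance model: the median was 0.71, 0.67 and 0.69 without OP50 replicate 1, 2 or 3, but 0 members passed without each of these and 0 with no mean-variance trend, against 25 and 21 without JUb19 replicate 1 or 3 and 28 with quantile normalization. Without an OP50 library, nos-2, cpg-1 and oma-2 had adjusted p between 0.0677 and 0.148. Of 83 sperm genes 10 fell and 0 rose, 60 and 0 adjusted over the list alone, with a median of -0.65. Among them msp-71 fell by 1.48 (SE 0.32) and sss-2 by 1.06 (SE 0.24), both listed as pseudogenes in the annotation, and the protein-coding gene spe-4 fell by 1.00 (SE 0.24). Sperm medians were -0.66, -0.26 and -1.06 in JUb19 replicates 1, 2 and 3. The list had adjusted p = 3.43e-14 by camera and adjusted p = 0.718 with an estimated correlation. Again 0 members passed without OP50 replicate 1, 2 or 3, at medians of -0.70, -0.61 and -0.67, 17 without JUb19 replicate 1 and 42 without JUb19 replicate 2, and 1 passed with no mean-variance trend and 19 with quantile normalization. The gene spe-4 lost its call without JUb19 replicate 3 (adjusted p = 0.0797). Among 32 genes of germline proliferation and meiosis 0 passed by limma, 10 higher adjusted over the list alone and 13 at an unadjusted p under 0.05, with a median of 0.29 (camera adjusted p = 1.74e-05, estimated correlation adjusted p = 0.718); mcm-3 had the smallest p, at 0.64 (adjusted p = 0.0573). In that list 9 members were higher without JUb19 replicate 1, 4 without JUb19 replicate 3, where the median was 0.19, and 10 with quantile normalization, and mcm-3 was called in each of these (adjusted p = 0.0249, 0.0297 and 0.0237).

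Cuticle collagens, the structural proteins of the worm's exoskeleton, fell in 16 of 128 members and rose in 2, or 31 and 2 adjusted over the list alone. The neighbouring genes col-126 and col-127 fell by 2.95 and 2.94 (SE 0.31 and 0.30), and col-170 fell by 2.53 (SE 0.35), while col-95 and col-135 rose by 1.59 and 1.58. The median was -1.0, with -0.09, -1.05 and -2.08 in JUb19 replicates 1, 2 and 3, so the spread within that group exceeded the change between the groups. Genes of moulting and the apical matrix had medians of 0.21, -0.64 and -1.15 in the same libraries, and hypodermis and seam markers had 0.05, -0.24 and -0.39. Of 25 moulting genes 1 fell, the transcription factor gene blmp-1, by 0.84 (SE 0.15), and 0 rose. Of 17 hypodermis and seam markers 0 passed by limma and 4 had an unadjusted p under 0.05. Camera placed neither list past the threshold (adjusted p = 0.216 and 0.139). Without JUb19 replicate 1 both passed (adjusted p = 0.000561 and 0.0458), with 12 and 5 members lower, and the moulting median was -0.07 without JUb19 replicate 3. The call of blmp-1 ended without OP50 replicate 1, 2 or 3 (adjusted p = 0.078, 0.0813 and 0.104). By camera the collagen list passed (adjusted p = 3.43e-09) and not with an estimated correlation (adjusted p = 0.718). Without JUb19 replicate 1, 82 members were lower and 7 higher with a median of -1.61, without JUb19 replicate 3 the median was -0.51, and without OP50 replicate 1, 2 or 3 there were 10, 5 and 9 lower and 1 higher in each case. The adult collagen gene col-19 stood at 2240 and 2140 CPM on JUb19 and OP50 (adjusted p = 0.845). The calls of col-95 and col-170 ended without OP50 replicate 2 (adjusted p = 0.0905 and 0.0503), that of col-95 also without OP50 replicate 1 or 3 (adjusted p = 0.0659 and 0.103). Vitellogenins, the yolk proteins made by the adult intestine, had 0 of 6 members past the threshold by limma and 0 at an unadjusted p under 0.05. Their medians on JUb19 were -1.55, -0.52 and 0.79 relative to OP50 in replicates 1, 2 and 3. Without JUb19 replicate 3 the list median moved from -0.39 to -1.01 (camera adjusted p = 0.00237), with 1 member lower, while without JUb19 replicate 1 it moved to -0.01 (camera adjusted p = 0.78, in the higher direction), and quantile normalization gave -0.14. For vit-2 the log2 fold change was -0.27 (SE 0.28, adjusted p = 0.517), and for vit-5 -0.75 (SE 0.50, adjusted p = 0.31), or adjusted p = 0.0481 without JUb19 replicate 3.

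**Figure D1:**
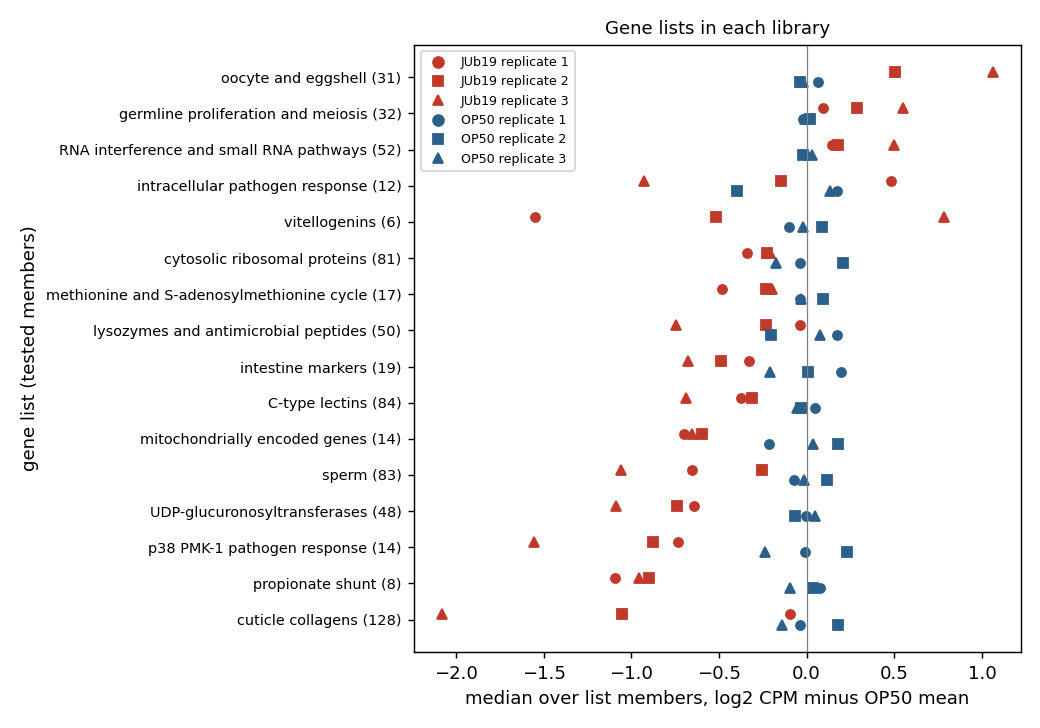
Median over the tested members of each gene list in every library, as log2 CPM minus the OP50 mean, with the number of tested members in parentheses. The 3 JUb19 libraries lie between -1.09 and -0.90 for the propionate shunt, whereas for vitellogenins they lie from -1.55 to 0.79, on both sides of OP50.

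Genes of defence against intracellular pathogens were examined because the series title concerns that defence. The intracellular pathogen response list, a set induced by microsporidia and viruses, had 12 tested genes of 44, and 0 rose or fell by limma, 0 adjusted over the list alone and 3 at an unadjusted p under 0.05. Its median log2 fold change was -0.18 (camera adjusted p = 0.739), with 0.48, -0.14 and -0.93 in JUb19 replicates 1, 2 and 3. Without JUb19 replicate 3 the median turned to 0.22 (adjusted p = 0.428) with 1 member higher, quantile normalization turned it to 0.04 with 1 member higher, and without JUb19 replicate 1 there were 2 lower at a median of -0.56. The filter on low values had left out pals-14, a member of this list and of the pals family: it had 41, 44 and 46 reads in the JUb19 libraries and 7, 6 and 17 in the OP50 libraries, and was called higher when no filter was used (adjusted p = 0.0352). It is named here after its values were seen. The regulators pals-22 and pals-25 stood at 3.06 and 1.94 CPM on JUb19 and 3.33 and 1.84 CPM on OP50 (adjusted p = 0.714 and 0.832). The cullin gene cul-6 had a log2 fold change of -0.45 (SE 0.30, adjusted p = 0.298), and Y94H6A.2 had the smallest p of the list (log2 fold change -1.31, adjusted p = 0.109). The reporter pals-5 was not analysed here. In the wider pals family, with pals-14 left out by the filter, 1 of 12 genes fell, 2 adjusted over the list alone: pals-17, by 1.38 (SE 0.26), which lost the call without OP50 replicate 1, 2 or 3 (adjusted p = 0.0698, 0.0944 and 0.0996). The family median was -0.26 (camera adjusted p = 0.226). Without JUb19 replicate 1 it was -0.56 with 4 members lower (camera adjusted p = 0.046), without JUb19 replicate 3 it was -0.11 with 1 higher, and quantile normalization turned it to 0.02 with 1 higher and 2 lower. Without OP50 replicate 1 or 2 it was -0.12 and -0.40.

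RNA interference genes had 0 of 52 members past the threshold by limma, 0 adjusted over the list alone and 25 at an unadjusted p under 0.05, with a median of 0.28. Camera put the list past the threshold (adjusted p = 0.000148) and not with an estimated correlation (adjusted p = 0.718), and its medians were 0.14, 0.18 and 0.50 in JUb19 replicates 1, 2 and 3. In the same libraries germline proliferation and meiosis genes had medians of 0.10, 0.29 and 0.55, and oocyte genes 0.50, 0.50 and 1.06. Replicate 3 was highest in each list, and the rise was not separated from that of germline genes. Without JUb19 replicate 1, 4 members were higher, without JUb19 replicate 2, 2 were lower, and without JUb19 replicate 3, 1 was higher and the median was 0.15. Quantile normalization gave 5 higher and 1 lower. The smallest p was that of the nuclear Argonaute gene nrde-3, at 0.69 (SE 0.17, adjusted p = 0.0531), which was called without JUb19 replicate 1 (adjusted p = 0.0355) and with quantile normalization (adjusted p = 0.0284). The double-stranded RNA channel gene sid-1 stood at 0.51 (SE 0.18, adjusted p = 0.102), the Argonaute gene rde-1 at 0.36 (SE 0.14, adjusted p = 0.12) and the RIG-I homolog gene drh-1 at 0.24 (SE 0.13, adjusted p = 0.212). The intestinal RNA import gene sid-2 stood at -0.20 (SE 0.27, adjusted p = 0.612), and at 0.12 without JUb19 replicate 3.

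Further lists passed the camera test in the lower direction. Intestinal markers fell in 4 of 19 genes, 8 adjusted over the list alone, with a median of -0.48, including the P-glycoprotein gene pgp-1, by 3.52 (SE 0.45), and the esterase gene ges-1, by 1.02 (SE 0.14), at adjusted p = 3.75e-05 and adjusted p = 0.673 with an estimated correlation. Genes encoded in mitochondrial DNA fell in 7 of 14, 12 adjusted over the list alone, with nduo-3 lower by 1.20 (SE 0.20), nduo-6 by 0.97 (SE 0.15) and the ribosomal RNA gene MTCE.33 by 0.91 (SE 0.20), at adjusted p = 2.39e-07 and adjusted p = 0.673 with an estimated correlation. Those 7 became 3, 0 and 1 without OP50 replicate 1, 2 or 3, 4 without JUb19 replicate 2 or 3 and 3 with no mean-variance trend, with adjusted p of 0.0671 and 0.0561 for nduo-6 without OP50 replicate 2 or 3. The gene nduo-3 lost its call without OP50 replicate 2 (adjusted p = 0.0755), and MTCE.33 without any library but JUb19 replicate 1 (adjusted p = 0.0567 to 0.168). MTCE.33 stood at 11.4 CPM on JUb19 and 21.3 CPM on OP50. How far ribosomal RNA was removed before sequencing was not examined, so its value need not reflect transcript level. Of the intestinal genes 2 were lower without OP50 replicate 2, where ges-1 had adjusted p = 0.0503, and 7 without JUb19 replicate 1. Ribosomal protein genes had a median of -0.27 with 1 of 81 lower, 0 adjusted over the list alone. The called gene was rpl-41.1, lower by 0.65 (SE 0.15). The list had adjusted p = 1.16e-07 by camera and adjusted p = 0.718 with an estimated correlation. The median was -0.16 without OP50 replicate 2 and -0.11 with quantile normalization, and the call of rpl-41.1 ended without any library but JUb19 replicate 1 (adjusted p = 0.0633 to 0.148). Vacuolar ATPase genes had 1 of 20 lower, vha-6, by 0.73 (SE 0.13), at adjusted p = 0.00106 and adjusted p = 0.718 with an estimated correlation. The gene vha-6 lost its call without JUb19 replicate 2 or OP50 replicate 1 or 2 (adjusted p = 0.0527, 0.0823 and 0.103), while quantile normalization gave 8 lower members. Body wall muscle markers had 0 of 21 past the threshold by limma and 10 at an unadjusted p under 0.05, a median of -0.38 and mup-2 at -0.58 (adjusted p = 0.0806), at adjusted p = 0.0324 for the list and adjusted p = 0.718 with an estimated correlation. That call ended without JUb19 replicate 1 or 2 or OP50 replicate 3 (adjusted p = 0.0742, 0.126 and 0.059), and the median was -0.19 without OP50 replicate 2 and -0.22 with quantile normalization. Neuron and pharynx markers had 0 of 24 and 0 of 12 past the threshold by limma, with 0 and 2 at an unadjusted p under 0.05 and medians of -0.04 and -0.07. Camera passed the neuron list in the higher direction without JUb19 replicate 3 (adjusted p = 0.0468) and the pharynx list in the lower direction without OP50 replicate 2 (adjusted p = 0.000694).

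Of the stress lists, that of oxidative stress and the SKN-1 pathway had members past the threshold. In it 4 of 21 genes fell and 0 rose, 4 and 1 adjusted over the list alone: gst-10, gst-4, the sulfide oxidoreductase gene sqrd-1, by 1.42 (SE 0.27), and cysl-2, a gene of the cysteine synthase family named after its values were seen (adjusted p = 0.0401). The median was -0.04 and the mean -0.26, with adjusted p = 0.369 by camera and adjusted p = 0.0292 by fry, which does not compare the list with other genes. Without OP50 replicate 1, 2 or 3 there were 2, 2 and 1 lower members and without JUb19 replicate 2 there were 2, and sqrd-1 lost its call without each of these libraries (adjusted p = 0.0509 to 0.116). The median ran from -0.10 to 0.01 when each library was left out. The chaperone genes hsp-4, of the endoplasmic reticulum, and hsp-6, of mitochondria, had log2 fold changes of 0.35 (adjusted p = 0.0936) and -0.07 (adjusted p = 0.701). With quantile normalization hsp-4 was called (adjusted p = 0.0322). The log2 fold change of hsp-70 was -1.21 (SE 0.50, adjusted p = 0.137). The heat shock, endoplasmic reticulum stress and mitochondrial stress lists had 0 called genes by limma, and 3, 4 and 1 at an unadjusted p under 0.05. The endoplasmic reticulum list passed camera in the higher direction without JUb19 replicate 2 or OP50 replicate 1 (adjusted p = 0.0268 and 0.0251), and 1 heat shock gene was higher without JUb19 replicate 1. Among 171 F-box and cullin adaptor genes 5 rose and 2 fell, with the Skp1-related genes skr-14, skr-15 and skr-7 higher by 2.02, 1.89 and 1.84. Of these, skr-14 and skr-7 lie close together on chromosome V and may share reads. Over all tested genes 5.48% were called. The adaptor list had a median of 0.09 and did not pass by camera (adjusted p = 0.373) or with an estimated correlation (adjusted p = 0.866). Without JUb19 replicate 1 there were 9 higher and 14 lower, and without JUb19 replicate 2 there were 3 and 1. Without OP50 replicate 1 there were 3 and 0, without OP50 replicate 3 there were 1 and 0, and quantile normalization gave 11 higher. Without OP50 replicate 2 the list had 0 calls, with adjusted p = 0.0813, 0.0672 and 0.0555 for these genes, and without OP50 replicate 3 skr-14 and skr-15 had adjusted p = 0.0691 and 0.0543. Without JUb19 replicate 3, skr-14 had adjusted p = 0.0533.

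**Figure D2:**
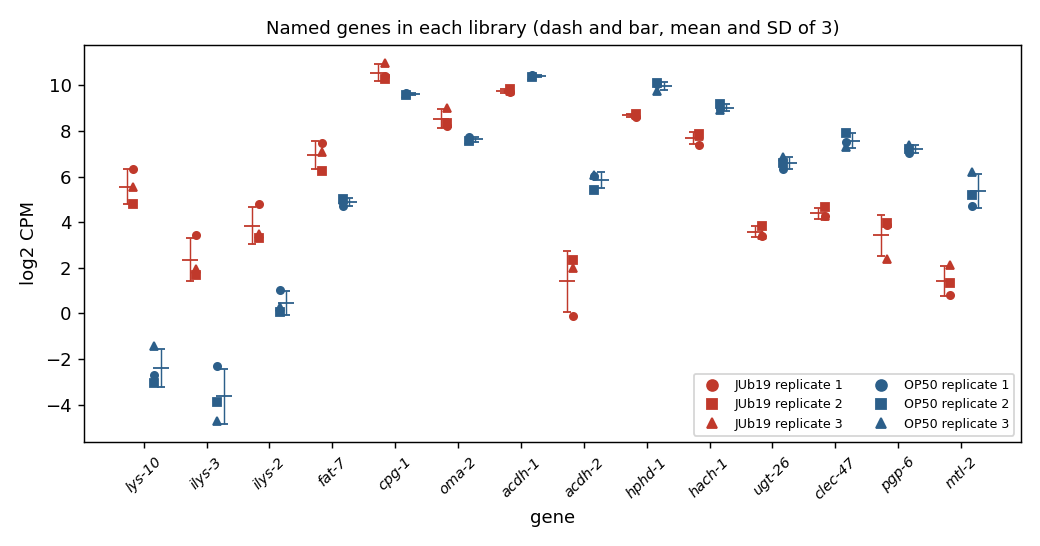
Log2 CPM of 14 named genes in each library, with the mean and SD of 3 libraries beside the points. For lys-10 the JUb19 libraries lie above all OP50 libraries by a log2 fold change of 7.95, and for acdh-2 they lie below, at a log2 fold change of -4.44.

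By camera 17 of 38 lists passed, 3 higher and 14 lower. With an estimated correlation 0 passed and 2 had an unadjusted p under 0.05, so these camera calls rest on the preset correlation of 0.01. The estimate rests on 6 libraries and has little power, so failing it does not show that a list was unchanged. Among the 17, fry in one direction passed the propionate shunt (adjusted p = 0.0115), UDP-glucuronosyltransferases and the methionine cycle (both adjusted p = 0.0292). Mitochondrially encoded genes, C-type lectins and intestinal markers also passed (adjusted p = 0.0432, 0.045 and 0.0476), the rest not. Fry does not compare a list with other genes. Splits of the 6 libraries that do not follow the food gave 13 to 21 lists past camera's threshold. Genes whose exons overlap another gene, such as inx-3, nos-2, acdh-2, gst-4, acs-1, nduo-3 and nduo-6, are uncertain. So are close copies, such as col-126 with col-127, pgp-5 with pgp-6 and the major sperm protein genes. The counting could split or merge the reads of such genes.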

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

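The vitellogenin covariate, the voom weights and log2(CPM + 1) were chosen after seeing the data. The main counts were 698 changed genes, 235 higher and 463 lower, with 17 lists past the threshold. Quantile normalization gave 1436 changed and 744 higher; no mean-variance trend gave 393, 95 and 298; requiring an absolute log2 fold change above 1 gave 387 changed, 275 of them lower. Array weights and robust variance, changed together, gave 5753, 2816 and 2937. The weight estimate stopped before reaching its tolerance and gave JUb19 replicate 2 a weight of 22.4 and JUb19 replicate 3 one of 0.137. On the JUb19 side that fit therefore rests mostly on 1 library. The weights and the robust variance were not run apart. The vitellogenin covariate gave 5534, 2677 and 2857; it was built from the same libraries and follows the spread among them. Voom weights gave 748 and log2(CPM + 1) 821. Leaving out each library gave 103 to 1713 changed, 15 to 618 higher, 88 to 1095 lower and 15 to 20 lists; the cause was not tested. In the settings run, 0 of the main calls turned direction. For most settings this was fixed in advance. The groups of all 698 genes did not overlap, so leaving out or weighting libraries could not turn a call. Nor could the filters or the variance trend, which leave the fold change as it was. Only a rescaling or the vitellogenin covariate could have turned one.

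With the replicate number as a replicate block, 1711 genes changed, 606 higher and 1105 lower, and 16 lists passed. The numbers gave no clear pairing of the samples. Same-numbered libraries correlated at 0.269, -0.047 and -0.016 in their deviations from the group means, and only replicate 1 correlated best with its own number. With 3 libraries per group these values do not exclude shared batches, so pairing stays open. The estimated correlation left 0 lists and fry in one direction 7.

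The intracellular pathogen response median of -0.177 turned to 0.04 with quantile normalization, and ran from -0.555 to 0.219 when each library was left out, the latter without JUb19 replicate 3. Genes that were not called turned sign as follows, and the cause was not tested. With quantile normalization hsp-6 was at 0.067, pals-22 at 0.133 and vit-2 at 0.18. With array weights and robust variance pals-22 was at 0.034. Over the left-out libraries the log2 fold change of col-19 ran from -0.029 to 0.194, below 0 without JUb19 replicate 2 or 3, that of sid-2 from -0.497 to 0.122, above 0 without JUb19 replicate 3, that of pals-25 from -0.044 to 0.275, below 0 without OP50 replicate 2, and that of metr-1 from -0.025 to 0.318, below 0 without OP50 replicate 3. Of 64 called named genes, 16 lost the call with no mean-variance trend, and 23, 34 and 28 lost the call without OP50 replicate 1, 2 or 3. Of the named genes that were not called, 5 gained a call with quantile normalization and 8 with the replicate block. Array weights and robust variance together added 21 such calls, the vitellogenin covariate 16 and the higher minimum 1. Without JUb19 replicate 1 or 3, 6 and 3 gained a call. The planned count tests on recovered whole reads were not run; the voom weights were the one fit on those reads. The planned pseudocounts applied to linear values only. Genes of low expression had been removed before deposit, which limits statements on them.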

Other observations

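Other genes were named here after their values were seen. W03F9.4, on chromosome V, had the steepest rise of the 12739 tested genes, with a log2 fold change of 9.33 (SE 0.47, adjusted p = 9.9e-05). The arginine kinase gene argk-1 fell by 5.27 (SE 0.34, adjusted p = 0.000165). On chromosome V the pud genes lie in a run from 2322038 to 2330930 (WBcel235), and 6 of them fell: pud-1.1 by 2.25, pud-1.2 by 2.37, pud-2.1 by 2.98, pud-2.2 by 2.75, pud-3 by 2.96 and pud-4 by 3.23. Genes of this run, such as pud-1.1 with pud-1.2 and pud-2.1 with pud-2.2, may share reads, so the 6 falls need not be separate observations. On the X chromosome pgp-7 fell by 3.69 between pgp-5 and pgp-6. On chromosome IV, log2 fold changes were -2.47 for dod-17, -2.53 for C32H11.4 and -3.03 for F55G11.2, all called, while dod-21 in the same stretch rose by 2.45 (SE 0.56, adjusted p = 0.043).

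The tests of list scaling, of a developmental advance and of other splits, and the limits on spread and on missing members in the early embryo tests, were chosen after the results were seen; the others were written before. Splitting the 6 libraries into 3 and 3 has 10 ways, too few for a share under 0.05. The other splits put both foods in each group, so a difference between foods adds to the spread within groups. Low gene counts there do not show what libraries without a food difference would give. The real split gave 698 changed genes, and the highest of the others 0 by limma, with at most 640 at an unadjusted p under 0.05 against 4126; for genes higher it was 235 against 0 and for genes lower 463 against 0, so 1 of 10 splits reached each count. For gene lists past the threshold 6 of 10 splits gave as many as the real 17, and the highest other gave 21. The number of lists past camera's threshold therefore does not separate the foods. Why the other splits passed so many lists was not tested.

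JUb19 replicate 3 stood apart from the other JUb19 libraries. Thinning all libraries to the depth of the shallowest left 1.01 of the gap on the first principal component, which argues against sequencing depth. Quantile normalization left 0.59 of it, so scaling between libraries cannot be told apart from other causes, since the bounds set were 0.5 and 0.9. A further developmental progress of these animals may be a candidate explanation, in view of the collagen and vitellogenin medians, and early embryo genes did not settle it: their median minus that in the higher of the other JUb19 libraries was -0.773, with quartiles over 13 genes from -1.06 to 0.32, and 24 of the 37 listed genes had no tested value, so it cannot be told apart.

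Oocyte genes higher with collagen and sperm genes lower kept direction and camera call in 3 of 3 lists after quantile normalization. The camera call says little here, since camera compares a list with the other genes, and a factor per library leaves that as it was. The medians were 0.71, -0.86 and -0.62, of both signs, which argues against scaling between libraries as the whole cause. For sperm, the median without major sperm protein genes was -0.634, which argues against reads shared between those copies. A uniform developmental advance on JUb19 may be a further explanation, but yolk genes go against it: in 2 of 3 JUb19 libraries vitellogenins lay below all OP50 libraries while oocyte genes lay above. The vitellogenin medians spread from -1.55 to 0.79 and the list did not pass (camera adjusted p = 0.373). Yolk genes may also respond to food, and food and collection time were not separated, so this cannot be told apart.

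Changed genes lay next to each other more often than random placement gives: 70 neighbouring pairs were called in one direction, against at most 40 in 10000 random placements. Pairs that share the part of the name before a hyphen or point were then removed. This takes out gene families, and also neighbours with systematic names such as C32H11.4, whose shared stem need not mean a family. Then 30 pairs remained, above 25, the upper bound set for random placements, but below their highest of 31. The fall does not measure family pairs alone. Reads shared within families may account for part and cannot be told apart from shared regulation. The hypothesis that JUb19 animals carried more embryos could not be tested well, since 24 of 37 early embryo genes had no tested value in a table filtered for low expression and larvae also express some of the other 13. Their median log2 fold change of -0.181 lay at percentile 51.7 of 10000 random lists matched on expression, with 1 gene past the threshold, so the hypothesis stays open.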
